A study of Mus musculus with 24 samples.

How the data were processed

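Nuclei were isolated from the lumbar spinal cord of adult mice of the outbred ICR/CD-1 stock, 8 to 11 weeks old, after removal of the dorsal root ganglia, and profiled by Drop-seq, a droplet method that tags each mRNA molecule with a unique molecular identifier (UMI), per the labels' protocols. The labels name the tissue as brain, while the protocol and the series title name the spinal cord; the values below are reported for spinal cord nuclei. The 24 samples were 9 control, 10 formalin and 5 rotarod mice, as the labels give them. Formalin mice received 30 µl of a 2% solution in the sole of each hindpaw, a standard painful stimulus, and rotarod mice walked on a rod accelerating to 40 rotations per minute over 5 minutes, a motor task. The time between stimulus and collection is not given in the sources used here.

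The authors deposited raw UMI counts for 32962 genes in 18000 barcodes, 750 per mouse, and a table that gives most barcodes a cell class and, for part of the neurons, a population. The genome builds in the submitters' processing notes are mm10 and GRCm38. The aligner, the gene annotation, and whether reads in introns were counted are not given in the sources used here. The counts have no stated strand, so overlapping genes on opposite strands and near-identical copies may share counts. Per the deposited annotation, 13425 nuclei fell in 7 classes, 3818 were discarded by the authors and 757 had no label. Doublets were not called again. The 43 neuron populations carry 8 family names, in which D, M and V were read as dorsal, mid and ventral, and E and I as excitatory and inhibitory; VC and VM were kept as codes. Dorsal families were DE and DI, ventral VE, VI, VC and VM, excitatory DE, ME and VE, and inhibitory DI, MI and VI, each family with equal weight. No barcode was left unmatched to a mouse.

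The mouse was the replicate. Raw counts were summed per mouse and class, for mice with at least 10 nuclei of the class, and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, its expression filter by group, robust fit) in R 4.3.3, with 1 fit over all 3 groups and Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 was the other tool. Reported CPM (counts per 1e6 UMIs) are means over mice of the UMIs of a gene or list scaled by all UMIs of the same cells, with the SD between mice. Gene lists were tested with camera (preset correlation of 0.01, and the estimated correlation) and fry from limma 3.58.1. Families were compared in control mice with the mouse as a block, at least 5 nuclei per mouse and family. Activity rates were the CPM of 23 rapid activity genes together in a class or family of a mouse, and were compared by two-sided exact permutation over mice, as were class shares. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and matplotlib 3.10.9 for the figures. Gene positions and spans come from GENCODE M21 on GRCm38.

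The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The lists were rapid activity, delayed activity, heat shock, glucocorticoid-responsive, inflammatory, neuropeptide, opioid, peptide and monoamine receptor, glutamate, GABA and glycine receptor, voltage-gated channel, transmitter identity, myelin, cholesterol synthesis, mitochondrially encoded, nuclear-retained long RNA, lumbar Hox, forebrain, dorsal root ganglion, blood, ribosomal protein and oxidative phosphorylation genes. For each neuron comparison the rule named the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 20 CPM in the higher group, without predicted or Riken-only symbols, up to 4 called members of each list, and always Fos, Arc, Egr1, Npas4, Junb and Nr4a1. Below 5 called genes, the 5 with the smallest p were given as values. For each other class it named 3 genes in each direction, and for families up to 5 genes per list in each direction. Other genes named were chosen after their values were seen. Some genes that the rule would name are not used here.

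Alternatives were DESeq2, its size factors in edgeR, no filter on low counts, at least 20 nuclei per mouse, only the 2 groups compared, leaving out the 3 control mice whose titles end in cx, thinning each nucleus to 500 UMIs, other activity lists and measures, and leaving out each mouse. The tests of activity genes in non-neuronal classes and discarded nuclei, of single activity genes, and of the UMI rate of each list were added after the data were seen, as were the pairs of formalin samples. Merging formalin samples 1 to 5 with samples 6 to 10 and removing a trend on gene span were added after seeing the data. So were leaving out formalin mice for class shares and for non-neuronal classes of formalin against rotarod mice, and adjusting the activity tests of classes and families again with each mouse left out. A sample's number gave no pairing of formalin with rotarod mice.

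The fits were tested on simulated counts with 200 changed genes, drawn from genes that passed the expression filter. Simulated samples were independent and had neither the resemblance of formalin pairs nor the span trend described below. Recovery in the deposited counts may therefore be lower. For neurons of formalin against control mice edgeR recovered 56.2% of genes changed 1.5-fold and 88.4% of those changed 2-fold, among 8775 genes. For rotarod against control mice these were 26.3% and 68.0% among 8782 genes, and for formalin against rotarod mice 30.1% and 78.8% among 8802 genes. In oligodendrocytes of rotarod against control mice they were 11.3% and 47.5% among 3032 genes. The simulation was first run after the first fits to the deposited counts. UMI totals ranged from 549903 to 3243587 per mouse and from 264921 to 2508457 over neurons, so genes with a few CPM rest on few molecules per mouse.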

Results

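The series profiled 24 mice, 9 of them controls, 10 injected with formalin in both hindpaws and 5 run on a rotarod, and asked which cell types make up the lumbar cord and which of them respond during these behaviours. Of the 13425 nuclei with a class, 7103 (52.9%) were neurons, 2184 oligodendrocytes, 1839 meningeal or Schwann cells, 1224 astrocytes, 727 endothelial or vascular cells, 183 oligodendrocyte precursors and 165 microglia. A neuronal nucleus held a median of 2214 UMIs and an oligodendrocyte nucleus 1092. Total UMIs per mouse averaged 1746368 ± 839069 (SD, n = 9) in controls, 1110664 ± 366631 (n = 10) in formalin and 1619181 ± 1083435 (n = 5) in rotarod mice. Discarded nuclei averaged 109 ± 108, 239 ± 114 and 89.6 ± 56.4 per mouse in the same order. Of the neuronal nuclei, 2082 of 3118 in control, 1209 of 2392 in formalin and 989 of 1593 in rotarod mice were placed in a population. Comparisons of neuron families and of discarded nuclei thus rest on unlike parts of each group's nuclei. Marker genes followed the deposited classes: oligodendrocyte markers reached 21557 CPM in oligodendrocytes against 1557 in neurons, and endothelial markers 12886 in endothelial or vascular nuclei against 46.3 in neurons. The oligodendrocyte precursor class held neuronal markers at 20219 CPM, against 8163 in oligodendrocytes. Microglia held neuronal markers at 11499 and oligodendrocyte markers at 8309 CPM, beside microglial markers at 871. Meningeal or Schwann nuclei held Schwann cell markers at 5229, astrocyte markers at 2424, meningeal markers at 2309 and ependymal markers at 651 CPM.

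The labels count the 10 formalin samples as separate mice. In neurons, however, samples 1 to 5 resembled samples 6 to 10 in numerical order: deviations from the group mean correlated at a mean of 0.265 within these pairs across 6038 genes, and 10 of 10 samples were closest to their partner. The 4 pairs of libraries within a group that were closest in summed counts were also such pairs, with a chi-square per degree of freedom of 1.32, 1.63, 1.72 and 1.79, against 2.17 for the next pair. The main tests kept the 10 samples that the labels count as mice. If the pairs share an animal, p-values that use 10 formalin samples are too small. Values with each pair merged into 1 unit are therefore given for part of the results. Among those not tested again in this way were the single activity genes other than Fos, Fos outside neurons and the rates of the other lists.

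Neurons of formalin mice held more Fos transcripts than those of control mice. Fos, an immediate early gene that marks recently active neurons, stood at 7.27 ± 3.30 CPM (SD, n = 10) in formalin and 0.960 ± 1.48 CPM (n = 9) in control mice, 7.58-fold, by exact permutation p = 9.7e-05, with an adjusted p of 0.00224 over the 23 genes of the list alone. The value was above the control median in 10 of 10 formalin samples, and it rests on 44 UMIs against 15. Fos lies on chromosome 12 from 85473890 to 85477273. With pairs merged into 5 units, Fos stood at 7.20 ± 1.13 CPM and the exact p was 0.0004995, the smallest that 5 against 9 allow. Fos was seen in 30 of 2392 neuronal nuclei of formalin mice. In oligodendrocytes of the same mice Fos stood at 0.520 CPM, from 1 UMI among 1218097. Fos was not limited to neurons: meningeal or Schwann nuclei of formalin mice held 12.2 ± 13.9 CPM (12 UMIs, against 0 UMIs in controls, exact p = 0.0186, adjusted p = 0.0743 over 4 classes), and astrocytes 2.32 CPM from 2 UMIs. Leaving out each mouse gave exact p values from 4.1e-05 to 0.000206, but the size of the ratio rested on few control UMIs. Control replicate 7 held 8 of them and control replicate 1 held 4, and 5 of 9 controls held 0. Without control replicate 1 the control mean was 0.634 CPM and the ratio 11.5, without control replicate 7 it was 0.661 CPM and 11.0, and leaving out any other mouse gave 6.74 to 8.13.

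The whole list of 23 rapid activity genes reached 97.1 ± 13.7 CPM (n = 10) in neurons of formalin mice and 72.9 ± 21.1 (n = 9) in controls, a log2 ratio of 0.41, with an exact permutation p of 0.00926 and an adjusted p of 0.0380 over 19 tests of classes. Among 93 tests of all lists in neurons its adjusted p was 0.215. Of its other members, the phosphatase gene Dusp1 had 3.55 against 0.936 CPM (exact p = 0.00557, list-adjusted 0.0641), and the transcription factor gene Egr1 11.4 ± 6.74 against 5.07 ± 2.93 CPM (exact p = 0.0144, list-adjusted 0.111). Npas4, which responds to calcium entry, had 8.62 against 6.20 CPM, Junb 4.93 against 2.30, Arc 2.03 against 1.28 and Nr4a1 5.23 against 6.52, with exact permutation p values of 0.325, 0.141, 0.321 and 0.372. The rise in the list was not detected after nuclei were thinned to 500 UMIs (log2 ratio 0.21, exact p = 0.415). The summed rate of the delayed activity genes ran the other way at -0.0784 (exact p = 0.121). That sum weighs abundant genes most, among them Sorcs3, which had a lower mean in formalin mice. Of the 12 delayed activity genes tested with edgeR, 8 had a positive and 4 a negative fold change. The 8 core genes alone gave a log2 ratio of 0.82 (exact p = 0.00200). With pairs merged the exact p for the list was 0.0490 before adjustment, too near 0.05 to pass adjustment over the 19 tests. Adjusted again over the classes with each of the 19 mice left out, the call was lost without 10 of them, with exact permutation adjusted p values up to 0.0724.

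Rotarod mice had 85.7 ± 10.4 CPM of the rapid activity genes in neurons (n = 5), a log2 ratio to control of 0.23 with an exact permutation p of 0.229. Fos stood at 3.28 ± 2.21 CPM, 3.42-fold over control (exact p = 0.0460, list-adjusted 0.515), and leaving out each mouse gave exact p values from 0.00839 to 0.124 and ratios from 2.88 to 5.17, the highest without control replicate 1 and the next, 4.96, without control replicate 7. Egr1 stood at 8.89 CPM, Npas4 at 11.3, Arc at 1.53, Junb at 2.59 and Nr4a1 at 9.35. The 8 core genes alone gave a log2 ratio of 0.64 over control (exact p = 0.0235). Formalin against rotarod mice gave a log2 ratio of 0.18 for the list (exact p = 0.127), 0.17 for the core genes (exact p = 0.396) and 2.22-fold for Fos (exact p = 0.0313, list-adjusted 0.360). The delayed activity genes stood at 730 ± 52.9 CPM in formalin and 832 ± 44.3 in rotarod mice, a log2 ratio of -0.19 that did not pass adjustment (exact p = 0.00400, adjusted p = 0.155 over 93 tests of lists). This too is a sum, and Sorcs3 alone fell by more CPM than the whole list. Of the 12 members tested with edgeR, 6 had a positive and 6 a negative fold change.

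**Figure D1:**
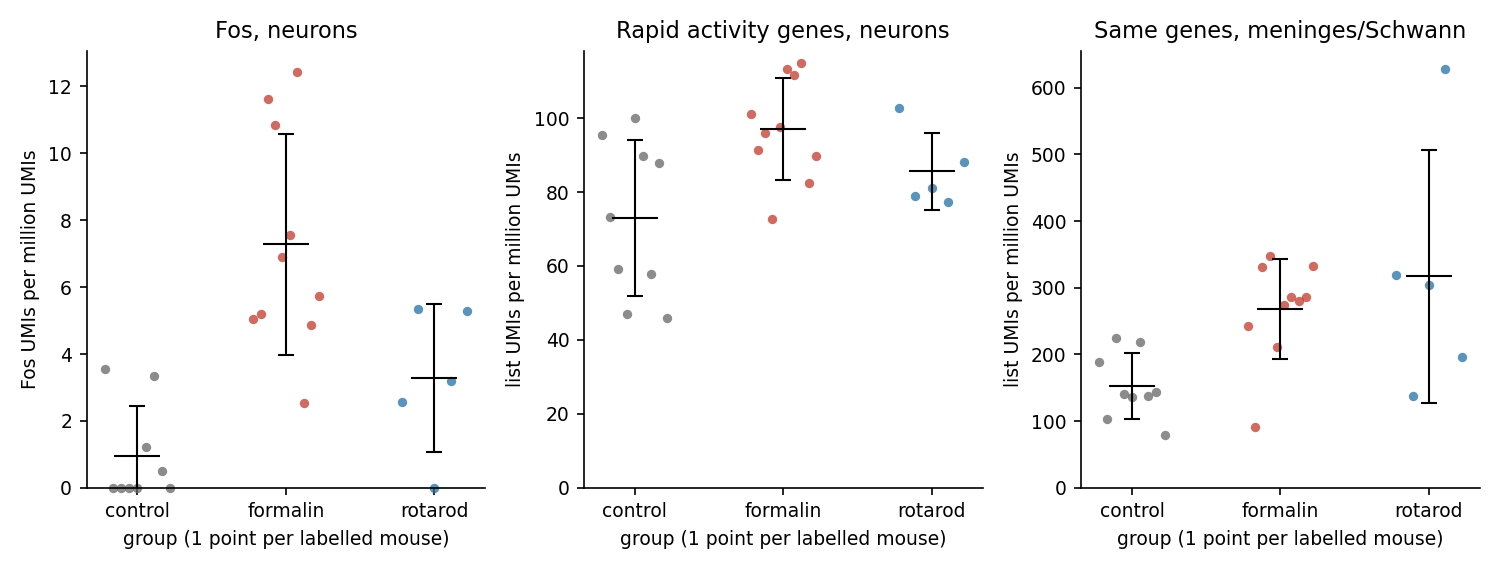
Fos in neurons (left), the 23 rapid activity genes in neurons (middle) and the same genes in meningeal or Schwann nuclei (right), in CPM on the vertical axes, by group on the horizontal axes. Each point is a labelled mouse, horizontal bars are group means and error bars SDs; Fos in neurons averages 7.27 in formalin, 0.960 in control and 3.28 in rotarod mice.

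By neuron family, only the mid inhibitory family MI passed adjustment, with a rise in formalin mice. Its rapid activity genes stood at 100.2 ± 29.5 CPM (n = 8) against 48.8 ± 27.8 (n = 9) in controls, with an exact permutation p of 0.00185 and an adjusted p of 0.0333 over 18 tests, and 38.8 ± 27.1 (n = 4) in rotarod mice. This call was lost without the 3 control mice whose titles end in cx (exact permutation adjusted p = 0.0599), with the 8 core genes alone (adjusted p = 0.370) and with nuclei thinned to 500 UMIs (adjusted p = 0.436). Leaving out each of 19 mice lost it without 12 of them, with adjusted p values up to 0.0818. Merged pairs gave 119 ± 44.8 (n = 5, exact p = 0.00150). These are not the same samples: formalin replicates 1 and 6, each left out above for fewer than 5 MI nuclei, entered as a merged unit. The list also stood higher in VC, at 144 ± 99.7 CPM (n = 8) against 66.4 ± 47.2 (n = 9) in controls (exact p = 0.0533, adjusted p = 0.273). DI stood at 110 ± 59.6 against 70.8 ± 39.9, and VI ran the other way, at 64.3 ± 38.8 against 85.3 ± 34.1. In MI, Fos had 2 UMIs in formalin and 0 in control mice. The dorsal inhibitory family DI held 17 of the 44 Fos UMIs of formalin neurons, 18.7 ± 17.5 CPM against 1.73 ± 3.86 in controls (exact p = 0.0150, adjusted 0.0900 over 6 families). With pairs merged, Fos in DI stood at 19.5 ± 16.4 CPM (n = 5, exact p = 0.00949 before adjustment). In the ventral excitatory family VE, Fos stood at 9.29 ± 9.01 CPM in rotarod mice (n = 3) and 0.518 ± 1.46 in controls (n = 8), with an exact p of 0.0121 and an adjusted p of 0.0727. Over dorsal neurons together the list stood at 95.5 ± 14.9 in formalin against 70.2 ± 30.0 in control mice, and over ventral neurons at 73.4 ± 25.3 against 68.4 ± 30.4. The dorsal-minus-ventral difference was not shown to differ between formalin and control mice (exact permutation p = 0.130). No single population passed in 114 exact tests, where the smallest adjusted p was 0.244, for VC-2 in formalin against control mice.

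**Figure D2:**
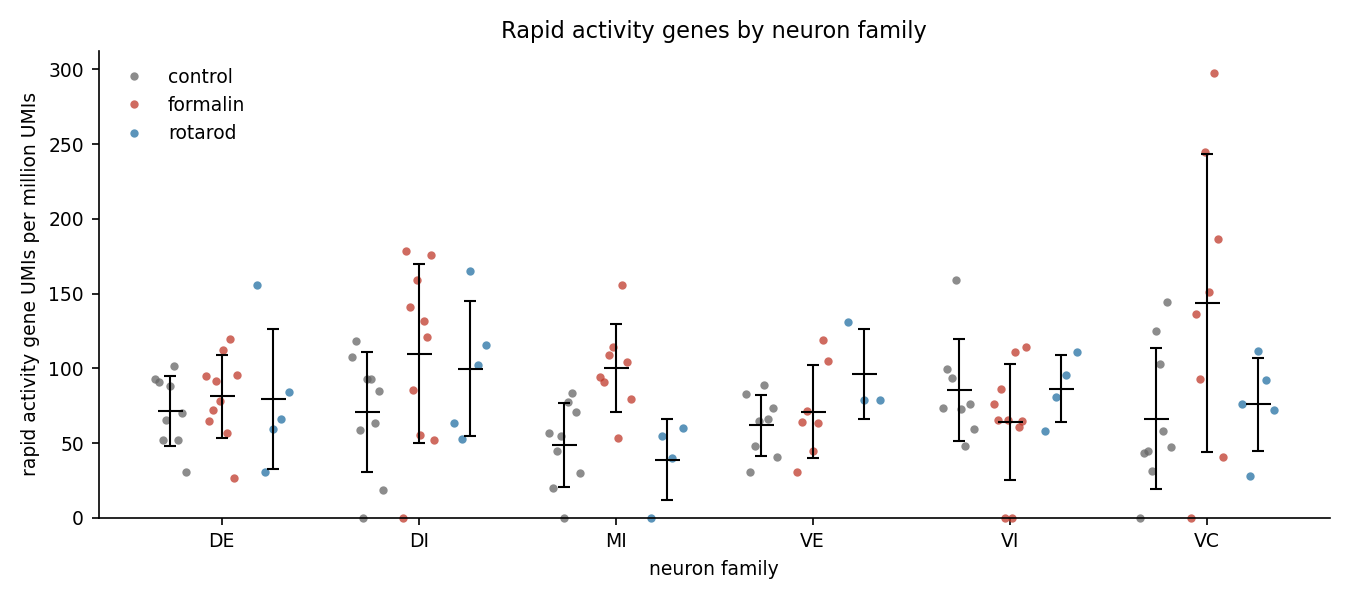
Rapid activity genes in 6 neuron families, in CPM on the vertical axis, by family on the horizontal axis and by group in colour. Each point is a labelled mouse with at least 5 nuclei of the family, bars are means and error bars SDs; in MI the formalin mean is 100.2 and the control mean 48.8.

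Meningeal and Schwann nuclei also carried more rapid activity transcripts after both stimuli. The list stood at 269 ± 74.9 CPM in formalin (n = 10), 317 ± 189 in rotarod (n = 5) and 152 ± 49.3 in control mice (n = 9), with adjusted p values of 0.0165 and 0.0380 by exact permutation over 19 tests. Nr4a1, an orphan nuclear receptor gene, rose in rotarod mice, to 41.5 ± 22.7 against 6.10 ± 8.53 CPM (exact p = 0.00200, list-adjusted 0.0460). Egr1 had 34.3 ± 23.0 CPM in formalin and 5.93 ± 6.59 in control mice (exact p = 0.00250, list-adjusted 0.0575). Cyr61, a secreted matrix protein gene induced in stimulated fibroblasts, had 44.0 and 39.7 CPM after formalin and rotarod against 7.89. Astrocytes, oligodendrocytes and endothelial or vascular nuclei did not pass in either comparison with control, with adjusted p values of 0.276 or more. The formalin call had an exact p of 0.00350 with merged pairs and passed without each mouse, with adjusted p values up to 0.0354 by exact permutation. The rotarod call was lost without 9 of 14 mice. Rotarod replicate 4 mattered most: without it the rotarod mean was 239 CPM, 86.8 above control instead of 165, with an exact p of 0.0420 and an adjusted p of 0.159.

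Among the 9103 of 32962 genes that passed the expression filter, few differences between neurons of formalin and control mice were detected. Fos had too few counts to pass this filter, so the number of calls does not bear on it. Too few rapid activity genes passed for a list test. Sorcs3, a sorting receptor gene of the delayed activity list, had 305 ± 42.3 CPM in formalin and 414 ± 64.7 in control mice, a log2 fold change of -0.43 (SE 0.10, edgeR adjusted p = 0.171). The noncoding Gm28905 had -0.63 (edgeR adjusted p = 0.110), Prr16 -0.41 and Hirip3, a histone-binding protein gene, 0.66, while Gm21092, a pseudogene whose counts are uncertain, had 1.27. edgeR called 0 of 9103 genes, with 766 at an unadjusted p under 0.05, and DESeq2 called 2, Gm28905 and Sorcs3; leaving out formalin replicate 5 gave 1 edgeR call, Gm28905. Adjusted over the list alone, 3 delayed activity genes passed with edgeR: Nrn1 and Rgs2 higher and Sorcs3 lower. Among lists, heat shock genes ranked up, with 5 of 6 members positive and none called, and myelin genes down, with 10 of 11 negative, each with a camera adjusted p of 0.0460. Neither held with an estimated correlation (adjusted p = 0.506 and adjusted p = 0.780). The other 13 lists tested, which were the delayed activity, glucocorticoid-responsive, receptor, neuropeptide, channel, transmitter identity, cholesterol synthesis, mitochondrially encoded, nuclear-retained, lumbar Hox, ribosomal protein and oxidative phosphorylation lists, had adjusted p values from 0.372 to 0.709.

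Neurons of rotarod mice likewise gave no edgeR call against control. The 5 genes with the smallest p each had an edgeR adjusted p of 0.0662. Cyb561, which encodes a vesicle cytochrome, had 26.5 ± 6.83 against 10.0 ± 4.67 CPM, a log2 fold change of 1.40. The values were -1.09 for Rogdi, -0.98 for Snx32, -0.96 for the mitochondrial ATPase gene Atad3a and -1.36 for 6330403K07Rik. edgeR called 0 of 9103 genes, with 782 at an unadjusted p under 0.05, and DESeq2 called 15. Leaving out control replicate 2 gave 11 calls, control replicate 9 gave 7, control replicate 6 gave 2, and control replicate 7, rotarod replicate 1 or rotarod replicate 2 gave 1.

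Gene lists in rotarod neurons moved with camera's preset correlation only. Oxidative phosphorylation genes ranked down, with 17 of 17 members negative (adjusted p = 7.6e-05, and adjusted p = 0.163 with an estimated correlation). Myelin genes ranked down, with 10 of 11 negative (adjusted p = 4.1e-06, and adjusted p = 0.163 with an estimated correlation); adjusted over the list alone, the myelin genes Cldn11, Mag and Mog were lower. Mitochondrially encoded genes ranked up, with 9 of 9 positive (adjusted p = 0.00865, and adjusted p = 0.638 with an estimated correlation). Voltage-gated channel genes ranked up, with 23 of 32 positive, and nuclear-retained long RNAs down, with 7 of 8 negative (adjusted p = 0.0350 each, and adjusted p = 0.163 each with an estimated correlation). The other 10 lists had adjusted p values from 0.239 to 0.818. Fold changes in this comparison rose with gene span (correlation 0.40 across genes), and the list tests did not correct for it. Myelin transcripts in neuronal nuclei may come from another cell type, and mitochondrially encoded transcripts are made outside the nucleus. The share of such carried-over RNA was not measured.

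The direct comparison of formalin with rotarod neurons gave the most calls, 196 of 9103 genes with edgeR (75 higher and 121 lower in formalin, 1617 at an unadjusted p under 0.05), and 263 with DESeq2. Higher in formalin mice were Slc22a17, a lipocalin receptor gene on chromosome 14 from 54906304 to 54913132 (73.2 ± 26.5 against 29.3 ± 9.38 CPM, log2 fold change 1.23, SE 0.24, edgeR adjusted p = 0.0104), the corepressor gene Tle2 (1.21), the importin gene Ipo4 (1.18), the inositol phosphatase gene Inpp5j (1.17), the SUMO protease gene Senp3 (1.15), Pank4 (1.13), the lysosomal ATPase gene Atp13a2 (1.12) and Ypel3 (1.08). Lower were the chromatin reader gene Cdyl (-1.23), the transcription factor genes Glis1 (-1.15), Hoxc4 (-1.05) and Lmx1b (-0.97), and Cyb561 (-1.13), Tspan18 (-1.07), Cryl1 (-1.001) and Hhat (-0.96). Lmx1b marks dorsal horn excitatory neurons, and it stood at 44.1 ± 10.3 against 95.8 ± 48.2 CPM.

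List members among these calls included receptor and channel genes. Sorcs3 was lower in formalin mice (305 ± 42.3 against 469 ± 34.4 CPM, log2 fold change -0.62, edgeR adjusted p = 0.00663), as were the L-type calcium channel gene Cacna1c (-0.58), the A-type potassium channel gene Kcnd3 (-0.52), the GABA-B receptor gene Gabbr2 (-0.43) and the NMDA receptor gene Grin2a (-0.41). Snhg11, an abundant noncoding RNA of neurons, was higher (0.50), as was Atp5a1 of the ATP synthase (0.57). Adjusted over each list alone, Homer1 was also lower, and Npy1r and Cox6a1 were also higher. Oxidative phosphorylation genes ranked up, with 15 of 17 members positive (camera adjusted p = 0.000287, and adjusted p = 0.331 with an estimated correlation), and mitochondrially encoded genes down, with 9 of 9 negative (adjusted p = 0.0106, and adjusted p = 0.699 with an estimated correlation). The other 13 lists had camera adjusted p values from 0.0675 to 0.687. In the fry test, voltage-gated channel genes moved down (adjusted p = 0.0226), with 22 of 32 negative.

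The fold changes followed gene span, so these gene names carry a limit. Called genes higher in formalin mice had a median span of 10.5 kb and those lower 305 kb, against 41.5 kb over all genes. The correlation of fold change with span across genes, which are not independent, was -0.49, and it was 0.40 for rotarod against control and -0.26 for formalin against control mice. Calls fell to 6 with a span trend removed, to 4 with formalin pairs merged and to 9 with nuclei thinned to 500 UMIs, and leaving out rotarod replicates 3, 2, 1, 5 and 4 gave 60, 82, 90, 118 and 123. Leaving out formalin replicates 8, 3, 4 and 9 gave 119, 120, 121 and 129. The log2 ratio of UMIs from genes above the upper quartile of span to UMIs from genes below the lower quartile was 1.73 in control replicate 9 and 2.34 in control replicate 2, so it varied within groups too.

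**Figure D3:**
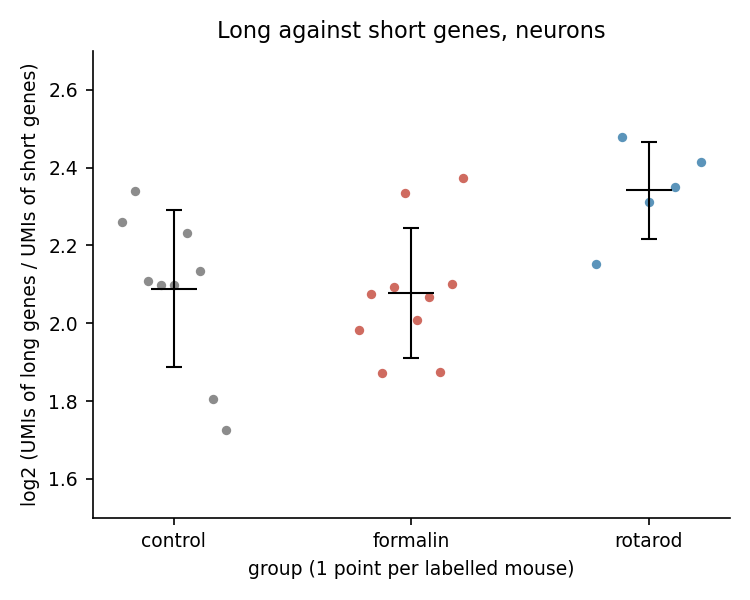
Log2 ratio of neuronal UMIs from genes above the upper quartile of span to those below the lower quartile, on the vertical axis, by group on the horizontal axis. Each point is a labelled mouse, bars are means and error bars SDs; the axis does not start at 0, and rotarod replicate 2 has the highest value, 2.48.

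Outside neurons, rotarod mice had 11 calls against control with edgeR, 7 of them in astrocytes. Astrocytes had more Atg4a, an autophagy protease gene (1057 ± 789 against 271 ± 108 CPM, log2 fold change 1.88, SE 0.35, edgeR adjusted p = 0.0112), more Hif3a, of the hypoxia-inducible factor family (393 ± 134 against 133 ± 72.3 CPM, 1.46), and more Upf2 of nonsense-mediated decay (1.45), Stxbp3, Snx9 and Daam2, and less Ccnl2, a cyclin gene (-1.63). Oligodendrocytes had more Cmss1 (288 ± 207 against 78.5 ± 30.8 CPM, 1.72). Meningeal and Schwann nuclei had more Il16, a cytokine gene (1.22), mt-Nd6 (1.68) and Gm13341 (3.07); mt-Nd6 overlaps a mitochondrial gene on the other strand and Gm13341 is a pseudogene, so both counts are uncertain. Endothelial or vascular nuclei had 0 calls with edgeR, 128 at an unadjusted p under 0.05 and 0 with DESeq2. Leaving out rotarod replicate 3 left 4 calls, control replicate 1 left 7 and rotarod replicate 1 left 7, and 500 UMIs per nucleus left 1.

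Formalin against control gave 0 calls with edgeR in each of 5 non-neuronal classes. Genes at an unadjusted p under 0.05 numbered 178 in oligodendrocytes, 187 in meningeal or Schwann nuclei, 82 in astrocytes, 56 in endothelial or vascular nuclei and 6 in oligodendrocyte precursors, and DESeq2 called 2 genes, Hif3a in astrocytes and Gm42418 in oligodendrocyte precursors. Hif3a had 321 ± 68.3 against 133 ± 72.3 CPM in astrocytes, a log2 fold change of 1.13 (edgeR adjusted p = 0.0685). Leaving out formalin replicate 1 gave 7 calls and formalin replicate 3 gave 4, all in the precursors, where 3 mice per group were measured, and formalin replicate 4, formalin replicate 7 or control replicate 2 gave 1. Microglia were in too few mice to test.

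Formalin against rotarod gave 24 calls in astrocytes, 15 in oligodendrocytes, 2 in meningeal or Schwann nuclei and 0 in endothelial or vascular nuclei with edgeR, the last with 128 at an unadjusted p under 0.05 and 0 with DESeq2. Astrocytes of formalin mice had less Atg4a (-2.75), Snx9 (-1.82) and Stxbp3 (-1.50) and more Atp1b2, a sodium pump subunit gene (1.89), and Ccnl2 (1.85). Oligodendrocytes had less Cmss1 (-1.46), Snx9 (-1.19) and Eif3a (-1.08) and more Atp1b1 (1.69), Atp6v0b (1.52) and Snhg11 (1.11). Meningeal or Schwann nuclei had more Snhg11 (1.11) and less mt-Nd6 (-1.83). Snhg11 is abundant in neurons and was also higher in neurons of formalin mice. Neuronal markers stood at 8163 CPM in oligodendrocytes and 8268 in meningeal or Schwann nuclei, so carried-over neuronal RNA was not excluded for Snhg11. With formalin pairs merged, the calls were 14 in astrocytes, 0 in oligodendrocytes, with 417 at an unadjusted p under 0.05, 1 in meningeal or Schwann nuclei, which was mt-Nd6, and 0 in endothelial or vascular nuclei. Leaving out each mouse gave 8 to 25 calls in astrocytes, the fewest without rotarod replicate 2, and 0 to 35 in oligodendrocytes, with 0 without rotarod replicate 3 and 35 without formalin replicate 10. The range was 1 to 7 in meningeal or Schwann nuclei and 0 to 3 in endothelial or vascular nuclei, the most in each without rotarod replicate 5.

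Shares of nuclei differed between the stimulus groups for 2 glial classes. Astrocytes made up 11.2% ± 1.24 of annotated nuclei in formalin (n = 10) and 6.98% ± 2.26 in rotarod mice (n = 5), with an exact permutation p of 0.000666 and an adjusted p of 0.0300 over 45 tests. Oligodendrocytes made up 20.6% ± 4.16 and 12.3% ± 3.50, with an exact p of 0.00200 and an adjusted p of 0.0450. No neuron family passed, and neither stimulus group was shown to differ from control, where these shares were 8.87% ± 4.72 and 15.9% ± 9.28 (n = 9). The controls were not alike. Astrocytes made up 10.2% to 14.0% in control replicates 1 to 5 and 0.988% to 6.34% in replicates 6 to 9. Oligodendrocytes made up 17.7% to 28.7% and 0.824% to 10.0%, so comparisons with the control mean could miss a difference. Shares depend on how nuclei were prepared, and neither call held without rotarod replicates 1, 3 or 5. With formalin pairs merged neither passed (smallest adjusted p = 0.179). Both then had an exact p of 0.00794, the smallest that 5 against 5 units allow, so merging could not decide these calls. The oligodendrocyte call was also lost without rotarod replicates 2 or 4 and without formalin replicates 1, 2, 5, 6, 8 or 10, while the astrocyte call stayed without each formalin mouse. Without rotarod replicate 4, endothelial or vascular cells passed between the same groups.

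In control mice, receptor and channel genes separated the dorsal from the ventral neuron families. Of 64 tested genes on the neuropeptide, receptor and channel lists, 28 were higher in dorsal and 11 in ventral families with edgeR, among 480 and 433 of 3072 genes. Calcium and potassium channel genes led the dorsal side: Cacna1g, a T-type calcium channel gene on chromosome 11 from 94408391 to 94474198 (log2 fold change 1.87, SE 0.18, edgeR adjusted p = 9.6e-16), Cacna1e (1.42), Kcnd3 (1.40), Kcnc2 (1.10) and Kcnq3 (0.75). Also dorsal were the glutamate receptor genes Grm3 (1.29), Grm5 (1.00), Gria1 (0.87) and Grm7 (0.73), the GABA-A receptor gene Gabra2 (0.88), the muscarinic receptor gene Chrm3 (0.61) and Penk, which encodes enkephalin (1.38). Of the 28 genes, 15 were higher in both DE and DI than in each of the 4 ventral families, among them Cacna1g, Cacna1e, Kcnc2, Grm3, Grm5, Grm7 and Gabra2. In VC, which was counted as ventral, Kcnd3, Kcnq3, Gria1 and Penk were not below both dorsal families. For Chrm3, DI was above each ventral family, but DE was below VE, VI and VM. On average over VE, VI, VC and VM, ventral families had more of the sodium channel genes Scn8a (-0.48) and Scn1a (-0.38), though not in VC, of the glutamate receptor genes Grm8 (-0.72) and Gria4 (-0.34), and of the receptor genes Adra1a (-0.97) and Htr2c (-0.91), with Gria4 and Htr2c in VC not above both dorsal families. Of the 11 genes, 3 were lower in both dorsal families than in each ventral family. Some ventral values rested on VC. In TMM-scaled CPM, the sodium channel gene Scn9a (-0.56) stood at 246 in VC, 63.0 in VE and 83.3 in DE, and the calcium channel gene Cacna1b (-0.24) at 519.6 in VC, 359 in VE and 411.5 in DE. Tacr1, the substance P receptor gene (-1.84), stood at 142 in VC, 71.8 in VI, 39.8 in VE, 56.0 in DE and 3.58 in DI, and was highest in ME, at 165.7, which is in neither group. Mitochondrially encoded genes were also higher in dorsal families, 8 of 8, as were 3 of 4 myelin genes. Dorsal nuclei were shallower, with a median of 2188 UMIs in DE and 2528 in DI. The ventral medians were 3081 in VC, 3142 in VI, 6192 in VE and 6829 in VM. Since the authors defined the families on these data, genes that separate them are not independent evidence.

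On the fixed lists, calcium channel subunit and transmitter genes differed between excitatory and inhibitory families, where edgeR called 122 of 3072 genes higher and 148 lower. Cacna2d1, the gabapentin-binding channel subunit gene, was higher in excitatory families (log2 fold change 2.56, SE 0.16, edgeR adjusted p = 1.5e-19) and Cacna2d3 in inhibitory ones (-1.74, SE 0.13). The vesicular glutamate transporter gene Slc17a6 (1.97) was higher in excitatory families, and Slc6a5 (-3.30) and Gad2 (-3.16), genes of glycine and GABA signalling, in inhibitory ones. Tacr1 (1.48), Gabra5 (0.95), Glra3 (0.73) and Grin3a (0.68) were higher in excitatory families, and the kainate receptor genes Grik3 (-1.02) and Grik2 (-0.92), Htr2c (-0.71) and Gria1 (-0.55) in inhibitory ones. Between the ventral families VE and VI the order did not hold for Tacr1, Gabra5, Grin3a, Grik2 and Gria1, so these differences rest on dorsal and mid families.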

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

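The tests of activity genes in classes other than neurons, in discarded nuclei and of list rates in neurons were chosen only after results had been seen; the rule for samples far from their group was not.

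In nuclei that the authors discarded, which the comparisons of cell classes do not use, rapid activity genes stood at 164 ± 40.0 CPM in rotarod mice (n = 5), 99.0 ± 31.2 in control mice (n = 9) and 97.5 ± 22.7 in formalin mice (n = 10), with a two-sided exact permutation p of 0.00549 for rotarod against control (adjusted p = 0.0348 over 19 tests) and of 0.000333 for formalin against rotarod (adjusted p = 0.00633, and exact p = 0.00794 with formalin pairs merged). With each mouse left out, the first of these was lost without 7 of 14 mice (adjusted p up to 0.0997 by exact permutation), and the second without none of 15.

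Of 93 groups of values, 9 held a sample whose gap to the nearest other sample passed Dixon's limit, which chance alone gives in about 1 of 20 groups. For the CPM of rapid activity genes, formalin replicate 8 stood at 109.6 in oligodendrocytes (others 38.3 to 73.4). Formalin replicate 2 stood at 91.3 in meningeal or Schwann nuclei (others 211.5 to 347.6). In endothelial or vascular nuclei, formalin replicate 10 stood at 1164 (others 274 to 665) and rotarod replicate 1 at 1553 (others 293 to 637). Endothelial or vascular cells made up 14.5% of the annotated nuclei of control replicate 9 (others 1.72 to 5.63), and microglia 3.26% of those of formalin replicate 6 (others 0.907 to 2.05). In neurons, mitochondrially encoded genes stood at 21387 CPM in control replicate 9 (others 3354 to 10163). Dorsal root ganglion genes stood at 62.0 in control replicate 7 (others 16.2 to 33.6), and blood genes at 2188 in formalin replicate 8 (others 17.8 to 713).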

How the results depend on the processing

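Merging formalin samples i and i+5 and removing a trend on gene span were chosen only after the results were seen. Apart from leaving out single mice, 84 settings were run: 53 left a result in the same direction and on the same side of its threshold, or a count within 1.5 times, 15 weakened it, 13 strengthened it and 3 reversed its direction. The causes were not tested unless named. The rise in rapid activity genes in neurons of formalin against control mice weakened with 500 UMIs per nucleus (log2 ratio 0.21), which leaves fewer molecules to count. It reversed with the summed delayed activity genes (-0.0784), other genes by construction, though 8 of 12 tested members had positive fold changes. Sorcs3 alone fell by more CPM than that sum, against control and against rotarod mice. Formalin against rotarod reversed with delayed activity genes (-0.19) and with 500 UMIs per nucleus (-0.19), and rotarod against control became stronger with the 8 core genes (0.64). Of neuron families, 2 passed with a mean over nuclei of each nucleus's rate, and 0 by exact permutation without the 3 cx control mice, with the core genes, with delayed activity genes and with 500 UMIs per nucleus. The smallest adjusted p of these settings ranged from 0.0178 for the mean over nuclei to 0.436 for 500 UMIs per nucleus, against 0.0333.

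For neurons of formalin against control mice edgeR's 0 calls became 2 with DESeq2 and 31 with no filter on low counts. For rotarod against control they became 15 with DESeq2, 43 with no filter, 1 with only the 2 groups in the fit, 3 without the cx mice and 2 with formalin pairs merged. For formalin against rotarod the 196 calls became 9 with 500 UMIs per nucleus, 4 with pairs merged and 6 with the span trend removed, and 45 with mice 1 to 5 of each group only, which has fewer mice. In non-neuronal classes, formalin against control went from 0 to 2 with DESeq2, 19 with no filter and 1 with pairs merged, and rotarod against control from 11 to 31 with no filter and 1 with 500 UMIs per nucleus. Camera made 9 list calls over the 3 comparisons, 0 with an estimated correlation; fry made 1, voltage-gated channel genes in formalin against rotarod mice, not among the 9. Of the 2 cell class shares, 1 passed among nuclei with at least 500 UMIs. With pairs merged 0 passed, though both stood at the smallest exact p possible. Counts of genes between neuron families, and of populations, stayed within 1.5 times or at 0 in the settings run.

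Leaving out each mouse moved the log2 ratio of the activity genes in neurons from 0.35 to 0.48 for formalin against control, from 0.16 to 0.30 for rotarod against control and from 0.15 to 0.25 for formalin against rotarod, where only leaving out formalin replicate 4 passed (exact p = 0.0455). Calls in neurons ranged from 0 to 1 for formalin against control (1 without formalin replicate 5). They ranged from 0 to 11 for rotarod against control: 11 without control replicate 2, 7 without control replicate 9, 2 without control replicate 6, and 1 without control replicate 7, rotarod replicate 1 or rotarod replicate 2. They ranged from 60 to 239 for formalin against rotarod: 60, 82, 90, 118 and 123 without rotarod replicates 3, 2, 1, 5 and 4, and 119, 120, 121 and 129 without formalin replicates 8, 3, 4 and 9. In non-neuronal classes they ranged from 0 to 7 for formalin against control: 7 without formalin replicate 1, 4 without formalin replicate 3, and 1 without formalin replicate 4, formalin replicate 7 or control replicate 2. They ranged from 4 to 14 for rotarod against control, with 4 without rotarod replicate 3 and 7 without rotarod replicate 1 or control replicate 1. Class shares that passed ranged from 0 to 2 over the 5 rotarod mice, with 0 without replicates 1, 3 or 5 and 1 without replicate 2, and from 1 to 2 over the 10 formalin mice, with 1 without replicates 1, 2, 5, 6, 8 or 10.

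Formalin and rotarod samples share replicate numbers 1 to 5. Deviations of same-numbered samples correlated at -0.02, 0.04, -0.11, 0.05 and -0.08, so the numbers give no pairing, and a fit with the replicate number as a block called 31 genes. Depth limits the single activity genes: the 44 Fos UMIs of formalin neurons come from 6025613 neuronal UMIs.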

Other observations

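The tests of the 3 patterns weighed here, the splits that keep formalin pairs together and the second draws of splits were chosen only after the results were seen.

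Of the neuropeptide genes, only Penk had enough counts to be tested between families, so the values here are untested means in control mice, several with an SD near or above the mean. In the dorsal excitatory family DE, Nts, which encodes neurotensin, stood at 59.2 ± 23.3 CPM (n = 9), Tac2 at 51.6 ± 45.6, Tac1, the substance P gene, at 34.6 ± 24.6, Cck at 33.0 ± 21.6 and Nmu at 26.8 ± 14.1, each its highest family mean. Sst stood at 65.4 ± 50.3 in DE, 56.2 ± 110.8 in MI and 36.1 ± 38.7 in ME. Npy was highest in the dorsal inhibitory family DI, at 34.3 ± 28.9 CPM against 4.14 ± 8.36 in DE. Penk stood at 105.8 ± 44.5 CPM in VC, 97.8 ± 141 in ME, 87.2 ± 54.4 in DE and 57.5 ± 59.6 in DI. Cartpt was highest in VC, at 33.2 ± 44.2, as were Chat and Slc5a7, genes of acetylcholine signalling, at 30.8 and 45.3 CPM.

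Receptor genes of pain and itch signalling were read from the same untested means. Npy1r stood at 31.3 CPM in DE and 8.13 in DI, and Grpr, an itch receptor gene, at 12.5 CPM in DE from 20 UMIs, with 0 UMIs in DI. The kappa opioid receptor gene Oprk1 stood at 83.7 ± 100.4 CPM in MI and at 18.9 ± 12.8 in DE, each from 35 UMIs. The mu receptor gene Oprm1 stood at 122 ± 120.8 CPM in ME, 111 ± 69.1 in VI, 74.2 ± 54.6 in DE and 70.5 ± 26.5 in DI.

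All lists, including those with few measured genes, were compared by their CPM in neurons, and none of 93 tests passed (smallest adjusted p = 0.155 by exact permutation), the rapid activity genes of formalin against control mice included (adjusted p = 0.215). Dorsal root ganglion genes stood at 17.3 ± 6.88 in formalin, 30.9 ± 12.8 in control and 23.1 ± 11.6 in rotarod mice (formalin against control exact p = 0.00270). Inflammatory genes stood at 31.6, 27.8 and 20.2, blood genes at 402, 83.5 and 126, and forebrain genes at 406, 428 and 459, in formalin, control and rotarod mice. Within neuron families, added after the data were seen, edgeR called 4 genes for formalin against rotarod in DI (among them Hoxc4, Snhg11 and Ttyh1), 1 for rotarod against control in MI (Dok5) and 4 for formalin against control in VE (Chst9, Luc7l3, Strada and Rnf220).

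Fos in neurons of formalin mice: RNA set free from other cells, such as meningeal or Schwann nuclei with Fos at 12.2 CPM, would give neurons and oligodendrocytes of a mouse the same rate, but Fos was higher in neurons in 10 of 10 mice (exact sign-flip p = 0.00195). With formalin pairs merged it was higher in 5 of 5 units, 7.20 ± 1.13 against 0.607 ± 1.36 CPM, where the smallest possible p is 0.0625. Counting shared animals as separate mice does not account for it either, since 5 merged units gave an exact permutation p of 0.0004995. Handling or processing that formalin mice share cannot be told apart from the stimulus, because no group was injected without the irritant; Fos in rotarod neurons, at 3.28 CPM, lay between the other groups. The stimulus itself stays open as the biological explanation.

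Formalin samples i and i+5 resemble each other: of 945 ways to pair the 10 samples, 1 had a mean correlation as high as that of these pairs, namely this one (exact p = 0.00106). The 5 pairs correlated at 0.37, 0.20, 0.19, 0.15 and 0.41, and 5 of 5 pairs were alike in Xist, the female-specific RNA. Each pair may therefore share a mouse or a preparation; the labels count 24 different mice, and no biological explanation for the order was tested.

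The 196 genes called in neurons of formalin against rotarod mice: with a trend on gene span removed, 6 passed. The median log2 fold change of 194 called genes with a span, in the called direction, went from 0.64 to 0.49 and the median SE from 0.16 to 0.15. A span trend could therefore account for most of the calls. Whether it accounts for the whole of the fold changes stays open, because these genes were chosen for their size. With formalin pairs merged 4 passed, and whether shared animals inflated the count cannot be told apart from the loss of units. Of 100 splits that kept the formalin pairs together, 2 gave as many calls, the real one included, and the highest other gave 249, with 18 others above 0, a sign of structure among the samples. A difference between the stimuli stays open.

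Other splits of the mice, 100 drawn per comparison and the real one included, show how many calls other groupings gave. For neurons of formalin against rotarod mice, splits that ignore the formalin pairs were drawn. Of these, 1 of 100 had as many calls as the real 196, and the highest other had 1 (27 in a second draw). Such splits part the pairs, and a split that kept them together gave 249. They cannot exclude chance if pairs share an animal, and do not show that the calls come from the stimulus. Chance cannot be excluded either for rotarod against control mice in non-neuronal classes, where 8 of 100 reached the real 11 and the highest other had 119. A second draw gave 2 of 100, with 20 as the highest other. Where edgeR's real count is 0 the splits decide nothing, since 100 of 100 reach 0 by construction: for neurons of formalin against control mice (766 genes at an unadjusted p under 0.05, 2 by DESeq2) the highest other had 5, for neurons of rotarod against control mice (782 and 15) it had 6, and for non-neuronal classes of formalin against control mice (2 by DESeq2) it had 228, which points to structure among the samples.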
